A study of Mus musculus with 6 samples.

How the data were processed

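Expression was measured in 6 libraries of cells sorted from mouse tumours, 4 of the ASTOM model (aP2-Cre with the R26 tdTomato and SmoM2 alleles) and 2 of the CST model (Cdh5-Cre with the same alleles). Per the labels' protocols, dissected tumours were digested with collagenase and dispase for 1 h at 37 °C, stained with an antibody against CD31 (the protein of Pecam1), and sorted as live, CD31-negative, tdTomato-positive cells. RNA of 1 ng was amplified into cDNA by single-primer isothermal amplification with a kit that does not keep strand, sheared to a target of 300 bp and made into libraries with unique dual indexes. Without strand, a gene and its antisense partner cannot be told apart, and overlapping genes can share reads. Amplification from 1 ng without molecular identifiers also means that reads are not independent molecules.

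The deposited files give, per gene and library, an expected count, a TPM value and an FPKM value, per the file headers. Per the submitters' processing notes the tools were Trim Galore 0.60, STAR 2.7.1a and RSEM 1.31 with the mm10 (GRCm38) mouse genome, and the annotation release and the RSEM settings are not given in the sources used here. The expected counts deposited by the authors are not whole where RSEM splits a read between genes, so a gene with a near-identical paralogue or pseudogene can gain or lose reads according to how they were split. The authors' TPM values were not used for any result. The FPKM values deposited by the authors were used once, to derive the mean fragment length they imply (172 to 188 bases in ASTOM, 196 and 141 in CST 5 and 6). The files list 55573 genes and 92 spike-in sequences, and the spike-ins, with 2 counts in CST 6 and 0 elsewhere, were left out. Coordinates are those of GENCODE M21 on GRCm38, taken for the 55094 gene identifiers whose version matches. Gene types are those deposited by the authors.

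Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr (minimum count 10, minimum total 15), and the quasi-likelihood fit and F test with model as the sole factor. P-values were adjusted by Benjamini and Hochberg over the 20991 genes that passed the filter, and an adjusted p under 0.05 counted as a call. Log2 fold changes are ASTOM minus CST, and their standard error is the size of the log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 0.562. CPM values use TMM-scaled library sizes. The floor for a gene with 0 counts in a model is 3 counts over that model's libraries, or 0.0198 CPM in ASTOM and 0.0416 CPM in CST, and the bound divides the other model's pooled counts, relative to its summed library sizes, by that floor. The TMM factors were 1.09 to 1.16 in ASTOM and 0.875 and 0.697 in CST.

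The test was checked on simulated counts with the real means and library sizes of these 20991 genes. It called 33 of 100 genes changed 4-fold and 93 of 100 changed 16-fold, 0 in the wrong direction, and 8 unchanged genes. In this simulation changes of 4-fold were therefore missed more often than found. No other genes were changed, and the changed ones all had a mean over 5 CPM. Far fewer genes changed than the 4669 called in the data, which makes the Benjamini-Hochberg threshold stricter. The shares found therefore do not carry over to the data, and how many such changes were missed there is not known. Of 100 lists of unchanged genes 1 had a camera p under 0.05. Genes were simulated independently of each other, so this does not check camera on lists whose genes vary together.

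The following choices were made before the data were examined. Gene lists numbered 39, and 826 of their 829 entries are in the files. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. With the correlation estimated per list 0 lists passed and 6 had an unadjusted p under 0.05, and 18 lists passed fry, a rotation test of whether a list's genes move, on balance, 1 way. Of the 27 lists that passed camera, 9 did not pass fry. They were the neutrophil (fry adjusted p = 0.0654), pericyte (0.0864), fibroblast and matrix (0.0918), histone (0.112) and adult myofibre lists (0.118). The others were the macrophage (0.139), tendon (0.161), class I (0.258) and cell cycle and mitosis lists (0.43). The named genes are Fabp4, Cdh5, Pecam1, Smo, Gli1, Ptch1, Myod1, Myog and Pax7 whatever their result. To these come the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among called genes, with models that do not overlap, a mean of at least 10 CPM in the higher model, and a symbol that is not a predicted gene, clone, mitochondrial gene or ribosomal pseudogene. Each list adds up to 3 called members with the smallest adjusted p, or up to 2 members with the highest CPM where none was called, and these may be summarised by count where the list does not pass. Other genes in the text, among them Mef2d, Cxcr4, Hhip, Spop, S100a8, S100a9, Ngp, Muc5b, mt-Cytb, mt-Co2, mt-Atp6, Col3a1, Fn1 and Sparc, were named after their values were seen. Some genes that the rule names are not reported here. Library measures were compared with two-sided exact permutation tests over the 15 splits of 6 libraries into 4 and 2, and the similarity of libraries with a one-sided one. With 15 splits no p can be below 0.0667.

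A fit without a library tests the genes that pass the filter there, so that the tested members of a list can differ. Alternatives comprised DESeq2 size factors, upper-quartile factors, no expression filter, a mean of at least 5 CPM, a test against a fold of 1.5, unrounded counts, removal of mitochondrial, ribosomal RNA and haemoglobin genes, the title number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom with and without sample weights, and for the lists an estimated correlation and fry. For the similarity they were the 500 most variable genes, Pearson correlation and a prior count of 0.5 in place of 2. Chosen after seeing the data were fits to genes with whole counts (within 0.005) in all libraries, to protein-coding genes, and to the 3 libraries with Y-linked counts. The total counts run from 23733400 to 63655800, so that 3 counts correspond to 0.0539 CPM in CST 5 and 0.182 CPM in CST 6. Model, library batch and processing batch cannot be told apart, because the labels give no batch that holds both models.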

Results

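The data were expression counts of cells sorted from the tumours of mice of 2 hedgehog-driven rhabdomyosarcoma models. In both, a Cre recombinase switched on SmoM2, an activated form of the hedgehog transducer Smoothened, together with the red reporter tdTomato. The ASTOM model carried aP2-Cre, driven by the promoter of the adipocyte gene Fabp4, and gave 4 libraries (replicates 5, 6, 7 and 8). The CST model carried Cdh5-Cre, driven by the promoter of the endothelial cadherin gene Cdh5, and gave 2 libraries (replicates 5 and 6). Cells were sorted as tdTomato-positive and negative for the endothelial protein PECAM1. The series was made to set known rhabdomyosarcoma models beside another tumour, which was not analysed here, so the comparison that these libraries allow is ASTOM against CST. Nothing in the labels says that the libraries of a model came from separate mice, and the p-values therefore measure the spread between these samples, which may be technical.

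Total expected counts were 33986000, 24685800, 43581000 and 31515000 in ASTOM 5, 6, 7 and 8, and 63655800 and 23733400 in CST 5 and 6. Despite the depth of CST 5, more genes had a count in ASTOM (26770 ± 501, SD, n = 4) than in CST (22260 and 22797). Ribosomal RNA genes other than mitochondrial ones took 3.38 to 7.12% of the counts in ASTOM, against 13.5% in CST 5 and 27.8% in CST 6. Mitochondrial ribosomal RNA took 17.0 to 24.0% in ASTOM and 21.4 and 11.9% in CST 5 and 6. The 10 highest genes held 30.9 ± 1.97% of the counts in ASTOM and 41.1 and 45.6% in CST. Counts that were not whole, which arise where a read fits several genes, made up 15.8 ± 0.273% of the detected genes in ASTOM and 31.6 and 33.3% in CST. In a two-sided exact permutation test the total count gave p = 0.667, and the number of genes with a count, the ribosomal RNA share, the share of the 10 highest genes and the share of counts that were not whole each gave p = 0.0667, the smallest p that the 15 splits of the 6 libraries allow, and 0.723 and 0.124 after Benjamini-Hochberg adjustment over 13 measures. Libraries of a model were also more alike than libraries of different models. The Spearman correlation across genes averaged 0.952 within ASTOM and was 0.884 between the CST libraries, against an average of 0.824 between models. The difference of 0.118 between the mean within-model and the mean between-model correlation was the largest of the 15 splits (one-sided exact permutation p = 0.0667, the smallest possible).

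Of 30 myogenic regulators 22 were higher in ASTOM, and of 30 embryonic and structural muscle genes 20. All 12 neutrophil markers and 9 of 16 lymphocyte markers were higher in CST, and the hedgehog targets Ptch1 and Gli1 did not pass the test. These 4 lists passed camera with a preset correlation, and 0 of the 39 lists passed with an estimated one. The neutrophil list did not pass fry (adjusted p = 0.0654). Of 20991 genes tested with edgeR's quasi-likelihood test, 2624 were higher and 2045 lower in ASTOM at a Benjamini-Hochberg adjusted p under 0.05. Among the 4669 genes that passed, the libraries of the models did not overlap in 4640, and 46.0% of all tested genes were separated in this way where chance gives 13.3%. Of the higher genes 1750 were protein-coding and 563 were pseudogenes, and of the lower genes 1603 and 138. These counts were 2415 higher and 1803 lower without ASTOM 5, and fell further without another ASTOM library. They were 1380 and 986 without ASTOM 6, 1072 and 703 without ASTOM 7, and 1016 and 697 without ASTOM 8. Such fits also hold fewer libraries, so that a fall in calls alone does not show that effects rested on a left-out library. Limma-voom with sample weights turned the split around, with 219 genes higher and 657 lower, so that 25% of its calls were higher against 56.2%. With these weights 33 of the 37 lists with a call had over 1.5 times fewer calls, among them the myogenic regulators (9 higher), the embryonic and structural muscle genes (2), the hedgehog genes (1), the neutrophil markers (5 lower) and the ribosomal protein genes (5 lower).

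Myogenic regulators, the transcription factors and receptors of muscle precursor cells, formed the list with the lowest camera p of the 39. Pax7, the transcription factor of muscle stem cells (ENSMUSG00000028736.13, GRCm38 chromosome 4, 139737062 to 139833528, minus strand), was at 75.1 ± 20.1 CPM (counts relative to the TMM-scaled library size, SD, n = 4) in ASTOM and at 0.934 and 0.908 in CST 5 and 6. The edgeR log2 fold change was 6.34 ± 0.443 (SE) with an adjusted p of 0.0019. Myod1, which commits cells to the muscle lineage, was at 28.8 ± 5.15 CPM in ASTOM and at 0 and 0.666 CPM in CST, a log2 fold change of 6.86 ± 1.33 with edgeR adjusted p = 0.0158. Myog, needed for muscle differentiation, was at 16.1 ± 5.89 CPM against 0.413 and 2.60 (log2 fold change 3.48 ± 0.826, edgeR adjusted p = 0.0268), and its adjusted p rose to 0.0645 without ASTOM 7 and to 0.0614 without ASTOM 8. Of the 30 regulators tested, 22 were higher and 1, Mef2d, was lower, with a median log2 fold change of 4.05. Adjusted over the list alone, 27 were higher and 1 lower. The list passed camera with a preset correlation (adjusted p = 9.48e-18) and not with an estimated one (adjusted p = 0.161 with an estimated correlation). Left-out libraries moved its median between 3.55, without CST 5, and 5.80, without CST 6, and Mef2d was not called without ASTOM 6, 7 or 8 or CST 6.

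Embryonic and structural muscle genes moved the same way, with 20 of 30 higher, 0 lower and a median of 3.51 (camera adjusted p = 8.57e-12, and adjusted p = 0.323 with an estimated correlation). Adjusted over the list alone, 23 were higher. Des, the muscle intermediate filament desmin, was at 127 ± 41.8 CPM in ASTOM and at 6.40 and 12.1 in CST (log2 fold change 3.79 ± 0.467). Actc1, the actin of heart and embryonic muscle, was at 156 ± 52.3 CPM against 7.60 and 4.60 (4.66 ± 0.494). Their edgeR adjusted p-values were 0.0056 and 0.0042. The number of higher genes was 8 without ASTOM 7 and 10 without ASTOM 8. Satellite cell markers had 7 of 15 higher, among them the Notch effectors Heyl and Hey1, and 1 lower, Cxcr4, which leukocytes also express (camera adjusted p = 0.000168, and adjusted p = 0.29 with an estimated correlation). Over that list alone the counts were also 7 and 1. There were 4 higher genes without ASTOM 8, 0 lower without ASTOM 6, 7 or 8, and 2 lower without CST 5. Markers of adult myofibres had 2 of 18 higher, both over all genes and adjusted over the list alone, with a median of 1.76 (camera adjusted p = 0.017, and adjusted p = 0.573 with an estimated correlation). Among all tested genes the share called higher, 2624 of 20991, was larger than in this list. Without CST 5 the adult skeletal myofibre markers had an adjusted p of 0.448, without CST 6 they had 10 higher genes and a median of 4.63, and without ASTOM 6, 7 or 8 they had 1 higher gene. Genes used as markers of rhabdomyosarcoma subtypes had 7 of 15 higher and 0 lower (9 adjusted over the list alone; median 3.18, camera adjusted p = 5.7e-06, and adjusted p = 0.181 with an estimated correlation), and 3 without ASTOM 7 or without ASTOM 8. Fgfr4, a growth factor receptor of muscle precursors, was at 18.8 to 29.1 CPM in the 4 ASTOM libraries and at 0 and 0.303 CPM in CST (log2 fold change 8.01 ± 1.17, edgeR adjusted p = 0.0084).

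**Figure D1:**
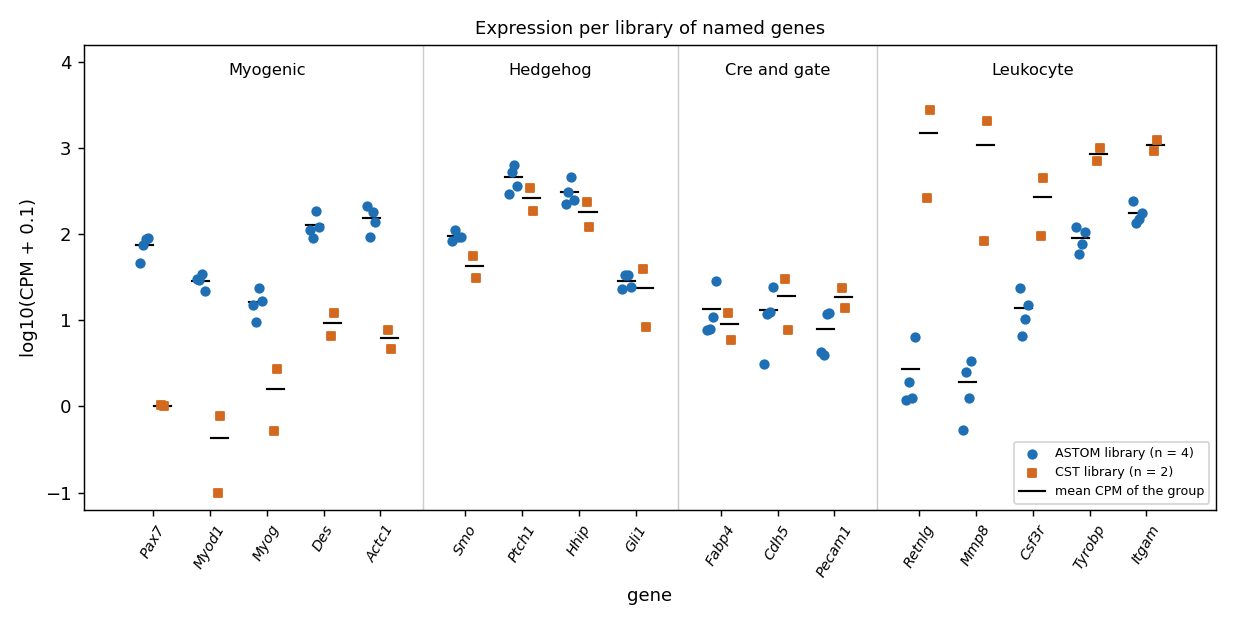
Expression of 17 genes in each library, as log10 of CPM plus 0.1, with circles for the 4 ASTOM libraries, squares for the 2 CST libraries and a bar at the log10 of each model's mean CPM plus 0.1. The myogenic genes separate the models (Pax7 46.7 to 90.9 CPM against 0.934 and 0.908), Ptch1, Hhip and Gli1 overlap or lie close, and the leukocyte genes are higher in CST (Retnlg 1.09 to 6.38 CPM against 263 and 2760).

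Hedgehog target genes were expressed in every library. Ptch1, the hedgehog receptor and the pathway's standard target, was at 455 ± 158 CPM in ASTOM and at 339 and 185 in CST, a log2 fold change of 0.80 ± 0.422 (edgeR adjusted p = 0.209). For Gli1, the target transcription factor, the values were 28.5 ± 5.87 CPM against 38.9 and 8.30 (0.27 ± 0.559, adjusted p = 0.762, and 1.81 with an adjusted p of 0.0179 without CST 5). Hhip, a target that binds hedgehog ligands and was added here after its values were seen, was at 313 ± 108 against 236 and 122 CPM (0.80 ± 0.413, adjusted p = 0.198). Smo itself (ENSMUSG00000001761.7, chromosome 6, 29735503 to 29761365, plus strand), whose counts can include reads from the SmoM2 transgene, was at 95.2 ± 12.6 CPM in ASTOM and 55.1 and 31.0 in CST (1.14 ± 0.303, edgeR adjusted p = 0.0364). Leaving out ASTOM 6, 7 or 8 or CST 6 raised that adjusted p to between 0.075 and 0.0885. As a list, the hedgehog pathway had 11 of 27 genes higher, led by the co-receptor gene Cdon (213 ± 32.1 CPM against 11.5 and 15.5) and the cilium genes Rab34 and Evc2 (adjusted p = 0.0562 for Evc2 without ASTOM 7), and 1 lower, Spop. Cdon also acts in muscle differentiation. Adjusted over the list alone 13 were higher and 1 lower, the median was 0.95, and camera gave an adjusted p of 0.00117 (adjusted p = 0.475 with an estimated correlation). The higher genes numbered 5 without ASTOM 6, 2 without ASTOM 7, 3 without ASTOM 8 and 6 without CST 6, the median was 1.65 without CST 5, and Spop was not called without ASTOM 6, 7 or 8 or CST 6.

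The genes whose promoters drove Cre, and the gene of the sorting gate, were not separated by the test. Fabp4, a fatty acid binding protein of adipocytes, was at 13.6 ± 9.88 CPM in ASTOM and 12.2 and 5.81 in CST (log2 fold change 0.59 ± 0.648, edgeR adjusted p = 0.545). Cdh5 (ENSMUSG00000031871.9, chromosome 8, 104101625 to 104144511, plus strand) was at 12.9 ± 8.81 CPM against 30.3 and 7.57 (-0.56 ± 0.795, adjusted p = 0.647), and Pecam1 at 7.93 ± 4.54 against 23.5 and 13.9 (-1.24 ± 0.56, adjusted p = 0.152). Endothelial markers did not pass as a list (4 of 30 higher, 0 lower, the same counts adjusted over the list alone, camera adjusted p = 0.417). The 4 higher genes included Prox1 (83.5 ± 12.8 CPM against 6.95 and 1.63), which is also expressed in muscle, Sox18 and Eng. Without CST 6 the list had 4 lower genes. Adipocyte markers did not pass (0 of 15 higher and 2 lower, Dgat2 and Pnpla2, on both adjustments; adjusted p = 0.304), with 0 lower without ASTOM 6, 7 or 8 or CST 6 (adjusted p 0.0566 to 0.144 for Dgat2 and 0.064 to 0.0915 for Pnpla2) and 5 without CST 5.

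Of 29 FGF, IGF and receptor kinase genes 12 were higher in ASTOM, and of 20 imprinted genes 14. Igf2, the imprinted fetal insulin-like growth factor, was among the most abundant transcripts there, at 2436 ± 1060 CPM against 38.1 and 74.3 in CST (log2 fold change 5.44 ± 0.647, edgeR adjusted p = 0.0051). Igfbp5, which binds it, was at 3554 ± 613 CPM against 169 and 114 (4.65 ± 0.431, adjusted p = 0.0034). Among the FGF, IGF and receptor kinase genes 0 were lower (17 higher and 1 lower adjusted over the list alone; median 1.71, camera adjusted p = 1.7e-06, and adjusted p = 0.323 with an estimated correlation), with 7 higher without ASTOM 7 or without ASTOM 8. Among the imprinted genes 0 were lower (16 higher and 0 lower adjusted over the list alone; median 2.49, camera adjusted p = 2.75e-11, and adjusted p = 0.155 with an estimated correlation), with 9 higher without ASTOM 8. Peg3 (580 ± 120 CPM against 51.8 and 57.0) and Dlk1 (8.11 ± 2.44 against 0.198 and 0.242) were among them. Genes of head mesoderm and jaw-arch muscle had 6 of 21 higher and 0 lower (12 adjusted over the list alone; median 3.38, adjusted p = 1.92e-06, and adjusted p = 0.155 with an estimated correlation), including Eya4 (37.9 ± 9.92 CPM against 1.51 and 3.81), which the myogenic list shares.

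The Notch, Wnt and BMP lists also passed camera with a preset correlation. The lists overlap, with 5 of 22 Notch, 10 of 30 myogenic, 7 of 15 satellite cell, 7 of 16 rhabdomyosarcoma, 7 of 29 FGF and IGF and 4 of 21 imprinted genes in another list, so that their calls are not separate results. Notch3 and Heyl are also myogenic list members, Heyl and Hey1 satellite cell markers, Fgfr4 a member of the myogenic, rhabdomyosarcoma and FGF lists, and Igf2 one of the rhabdomyosarcoma, FGF and imprinted lists. Notch pathway genes had 5 of 20 higher and 0 lower on both adjustments, with a median of 0.56 (camera adjusted p = 0.0168, 0.11 without CST 6, and adjusted p = 0.323 with an estimated correlation), and a median of 0.36 without ASTOM 8 and of 1.34, with 3 genes lower, without CST 5. Notch3 was at 208 ± 37.3 CPM against 14.3 and 11.4, and Heyl at 385 ± 61.2 against 21.1 and 13.7. Wnt pathway genes had 6 of 23 higher and 0 lower (12 and 0 adjusted over the list alone; median 1.39, adjusted p = 0.000354, and adjusted p = 0.385 with an estimated correlation), with 10 without ASTOM 5 and 3 without ASTOM 7 or ASTOM 8. The members that led were Wif1 and Dkk2, which are secreted inhibitors of Wnt signalling, and the ligand gene Wnt5a. BMP and TGF-beta genes had 9 of 25 higher and 1 lower (11 and 1 adjusted over the list alone; median 1.29, adjusted p = 0.00225, and adjusted p = 0.323 with an estimated correlation), led by Id3, Tgfb2 and the BMP antagonist gene Grem1. The lower genes numbered 0 without ASTOM 7 or ASTOM 8 and 2 without CST 5.

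Matrix genes were abundant in ASTOM, where Col3a1, Fn1 and Sparc were among the 10 highest protein-coding genes of each library. Fibroblast and matrix genes had 14 of 30 higher and 0 lower (20 and 1 adjusted over the list alone) and a median of 1.74 (camera adjusted p = 1.28e-05, and adjusted p = 0.52 with an estimated correlation). Their summed level was 33605 ± 13601 CPM in ASTOM and 12522 and 10982 in CST. Without ASTOM 6, 7 or 8 or CST 6 the higher genes numbered 7, 5, 3 and 7. Pericyte and smooth muscle markers had 7 of 15 higher and 0 lower, including Des, Pdgfrb (236 ± 58.5 CPM against 43.2 and 52.0) and Acta2 (8 adjusted over the list alone; median 1.70, adjusted p = 0.00169, and adjusted p = 0.509 with an estimated correlation), and 3, 2, 2 and 3 without the same 4 libraries. Acta2 had adjusted p-values of 0.0507, 0.064 and 0.0649 without ASTOM 6, 7 and 8. Tendon markers (2 of 10 higher on both adjustments, median 2.66, adjusted p = 0.0358, and adjusted p = 0.573 with an estimated correlation) had an adjusted p of 0.23 and 1 higher gene without CST 5, 4 higher genes without CST 6 and 0 without ASTOM 6, 7 or 8. Cartilage and bone markers had 3 of 15 higher on both adjustments (median 2.03, adjusted p = 0.00908, and adjusted p = 0.399 with an estimated correlation), with 1 without ASTOM 5, 0 without ASTOM 6, 7 or 8, 6 without CST 5 and 5 without CST 6. Neuronal markers had 2 of 8 higher on both adjustments, Dcx and Map2 (median 1.78, adjusted p = 0.00908, and adjusted p = 0.323 with an estimated correlation), with a median of 4.81 over 11 genes that passed the filter without CST 5 and 1 higher gene without ASTOM 6, 7 or 8. The adjusted p of Map2 lay between 0.0551 and 0.0694 without ASTOM 6, 7 or 8 or CST 6.

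Neutrophil genes were higher in both CST libraries. Their summed level was 98.7 ± 65.8 CPM in ASTOM, 2656 in CST 5 and 70687 in CST 6, where the calprotectin genes S100a9 (24335 CPM) and S100a8 (14450 CPM) were the highest protein-coding genes. In CST 5 these 2 genes, named here after their values were seen, stood at 1118 and 648 CPM. Retnlg was at 2.61 ± 2.53 CPM in ASTOM against 263 and 2760 (log2 fold change -9.18 ± 1.21, edgeR adjusted p = 0.0066), and the collagenase gene Mmp8 was at 1.82 ± 1.26 against 82.5 and 2059 (-9.21 ± 1.35, adjusted p = 0.0084). All 12 neutrophil markers were lower in ASTOM, also when adjusted over the list alone, with a median of -8.66 (camera adjusted p = 1.84e-07, and adjusted p = 0.399 with an estimated correlation). The count was 3 without ASTOM 6, 4 without ASTOM 7, 5 without ASTOM 8 and 4 without CST 6, where the median was -4.17.

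A part of the lymphocyte and macrophage genes was also higher in CST, and macrophage genes were abundant in all 6 libraries. The macrophage and monocyte markers summed to 11049 ± 5938 CPM in ASTOM, and to 34873 and 13022 in CST 5 and 6, with ASTOM 5 (19722) above CST 6. In CST 5 the list members Lyz2 (5891 CPM), Cd74 (5472 CPM), H2-Aa and H2-Ab1 were the highest protein-coding genes other than mitochondrial ones. Cd74 and Lyz2 were also the highest in ASTOM 5 (5160 and 4740 CPM). These genes were named after their values were seen. Differences between the models may reflect the mix of sorted cells, which was not tested. Tyrobp, a signalling adaptor of myeloid cells, was at 90.6 ± 28.1 CPM against 702 and 993 (log2 fold change -3.23 ± 0.342, edgeR adjusted p = 0.0042), and Itgam, the integrin CD11b, at 175 ± 47.8 against 929 and 1254 (-2.64 ± 0.309, adjusted p = 0.0049). Of the 26 markers 0 were higher and 7 lower on both adjustments, with a median of -1.11 (camera adjusted p = 2.25e-05, and adjusted p = 0.475 with an estimated correlation). The macrophage and monocyte markers rested on CST 5, since without it the median was 0.92 and the adjusted p 0.486. The lower markers numbered 4 without ASTOM 6, 7 or 8 and 13 without CST 6, where the median was -1.78. Lymphocyte markers had 0 of 16 higher and 9 lower (11 adjusted over the list alone; median -3.96, adjusted p = 1.7e-06, and adjusted p = 0.155 with an estimated correlation), and 5, 4 and 5 without ASTOM 6, 7 and 8. Their levels were low, at 92.1 ± 25.5 CPM in sum against 369 and 593.

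Lists that follow cell stress, cell handling or RNA quality held genes that were lower in ASTOM, in most of these lists a minority of the members. Immediate early and dissociation genes, which tissue digestion can induce, had 10 of 26 lower and 1 higher (15 and 1 adjusted over the list alone; median -1.27, camera adjusted p = 4.4e-05, and adjusted p = 0.399 with an estimated correlation). Nr4a1 was at 39.7 ± 20.5 CPM against 251 in each CST library. The lower genes numbered 4 without ASTOM 5 or 6, 2 without ASTOM 7 and 6 without CST 6, and the higher ones 0 without ASTOM 5, 6, 7 or 8 and 3 without CST 6. Cytosolic ribosomal protein genes had 20 of 35 lower and 0 higher (25 adjusted over the list alone; median -0.90, adjusted p = 1.41e-08, and adjusted p = 0.462 with an estimated correlation), and 8, 5, 4 and 13 without ASTOM 6, 7 and 8 and CST 5. Their reads can be shared with many pseudogenes, and 1 of the 35 had whole counts in all libraries. Replication-dependent histone genes had 10 of 24 lower and 0 higher (11 adjusted over the list alone; median -1.94, adjusted p = 2.78e-06, and adjusted p = 0.462 with an estimated correlation), and 6, 5, 3 and 4 lower without ASTOM 5 to 8, 16 without CST 5 and 5, with a median of -0.36, without CST 6. Nuclear oxidative phosphorylation genes had 9 of 34 lower and 1 higher (11 and 1 adjusted over the list alone; median -0.46, adjusted p = 0.00214, 0.0658 without CST 5, and adjusted p = 0.475 with an estimated correlation), and 4, 2, 2 and 3 lower without ASTOM 5, 6, 7 and 8, with 0 higher without those libraries or CST 5.

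Mitochondrially encoded genes had 6 of 13 lower and 0 higher on both adjustments (median -1.15, camera adjusted p = 2.49e-08, and adjusted p = 0.323 with an estimated correlation). Within the list the values were uneven. The oxidase subunit gene mt-Co3 was at 0.636, 0, 0.0401 and 0.406 CPM in ASTOM 5 to 8 and at 1313 and 931 in CST, while mt-Cytb was at 2222 ± 295 CPM against 3163 and 1412. The dehydrogenase subunit gene mt-Nd3 was at 4.70 ± 1.56 CPM against 82.7 and 52.0 (log2 fold change -3.84 ± 0.354, edgeR adjusted p = 0.00337), with whole counts in all libraries. Near-identical copies of mt-Co3 and its neighbours lie in the nuclear genome, so that mt-Co3, mt-Co2, mt-Atp6 and mt-Atp8 are uncertain here. The difference in mt-Nd3, also a neighbour of mt-Co3, may be uncertain too. Gm28438, beside the copies on chromosome 1, was at 3.13, 2.94, 6.11 and 4.96 CPM in ASTOM 5 to 8 and at 0 in CST. These levels, if added to mt-Nd3, are too low to bring it to its level in CST. The 9 genes other than mt-Co3, mt-Co2, mt-Atp6 and mt-Atp8, mt-Nd3 among them, had 2 lower and a median of -0.75. In the fit to genes with whole counts, chosen after seeing the data, 1 of 6 was lower with a median of -0.63. Without CST 5 the median was -0.26, and without CST 6 there were 10 lower genes.

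Cell cycle and mitosis genes had 2 of 34 lower, E2f1 and Cenpa, and 0 higher (1 lower adjusted over the list alone), with a median of -0.81 (camera adjusted p = 0.00767, and adjusted p = 0.689 with an estimated correlation). The direction rested on CST 6, with a median of 0.59 and 3 higher genes without it, and of -1.29 with 13 lower genes without CST 5, and there were 0 lower genes without ASTOM 6, 7 or 8. E2f1 had an adjusted p of 0.051 to 0.0562 without those ASTOM libraries, and Cenpa of 0.0533 to 0.102 without any of the 6 libraries. Among all tested genes the share called lower, 2045 of 20991, was larger than in the cell cycle list and in the class I list. Class I antigen presentation genes had 1 of 17 lower, H2-D1, and 0 adjusted over the list alone (median -1.01, adjusted p = 0.00487, and adjusted p = 0.573 with an estimated correlation). Without CST 5 the median was -0.04 and the adjusted p 0.808, and there were 4 lower genes without ASTOM 5 or CST 6 and 0 without ASTOM 6, 7 or 8, where the adjusted p of H2-D1 was 0.0812, 0.0988 and 0.0987 (0.114 without CST 5).

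The remaining lists did not pass camera. Higher and lower genes numbered 5 and 0 of 29 interferon response genes (adjusted p = 0.623), 1 and 3 of 24 hypoxia genes (adjusted p = 0.133), 3 and 5 of 20 p53 targets (adjusted p = 0.2) and 1 and 3 of 17 cyclins, Myc family genes and cell cycle inhibitors (adjusted p = 0.796). For the Hox genes they were 4 and 5 of 25 (adjusted p = 0.38), for Schwann cell markers 3 and 1 of 14 (adjusted p = 0.0973), for keratinocyte and epithelial markers 2 and 0 of 13 (adjusted p = 0.15) and for erythroid markers 1 and 0 of 10 (adjusted p = 0.4). Of 8 salivary gland markers and 5 sex-linked genes 0 passed edgeR (camera adjusted p = 0.38 and 0.262), 1 of each had an unadjusted p under 0.05, and DESeq2 called 5 salivary gland markers and 1 sex-linked gene higher. Adjusted over the list alone the counts were the same, except for 1 lower hypoxia gene, 4 higher Schwann cell markers and 3 higher epithelial markers. Single left-out libraries brought some of these lists past the threshold, namely hypoxia genes (without ASTOM 7 or CST 5), interferon response genes (without CST 5), Schwann cell markers (without ASTOM 5), epithelial markers (without CST 6) and sex-linked genes (without ASTOM 6). The counts also moved, to 6 higher Schwann cell markers without ASTOM 5, 4 higher epithelial markers without CST 5 (and 1 lower) or CST 6, 1 without ASTOM 5 or 6 and 0 without ASTOM 7 or 8, and 1 higher and 4 lower sex-linked genes without ASTOM 6. Lower hypoxia genes numbered 7 without CST 5, 1 without ASTOM 5 or 7 and 0 without ASTOM 6, ASTOM 8 or CST 6, and higher ones 2 without CST 5 and 0 without ASTOM 6, 7 or 8 or CST 6. Higher interferon genes numbered 9 without CST 5, 2 without ASTOM 6 or 7 and 3 without ASTOM 8, with 2 lower without ASTOM 5 or CST 5. Lower p53 targets numbered 3, 1 and 2 without ASTOM 6, 7 and 8, and cyclin-list genes 5 higher and 5 lower without CST 5 and 2 higher without CST 6.

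**Figure D2:**
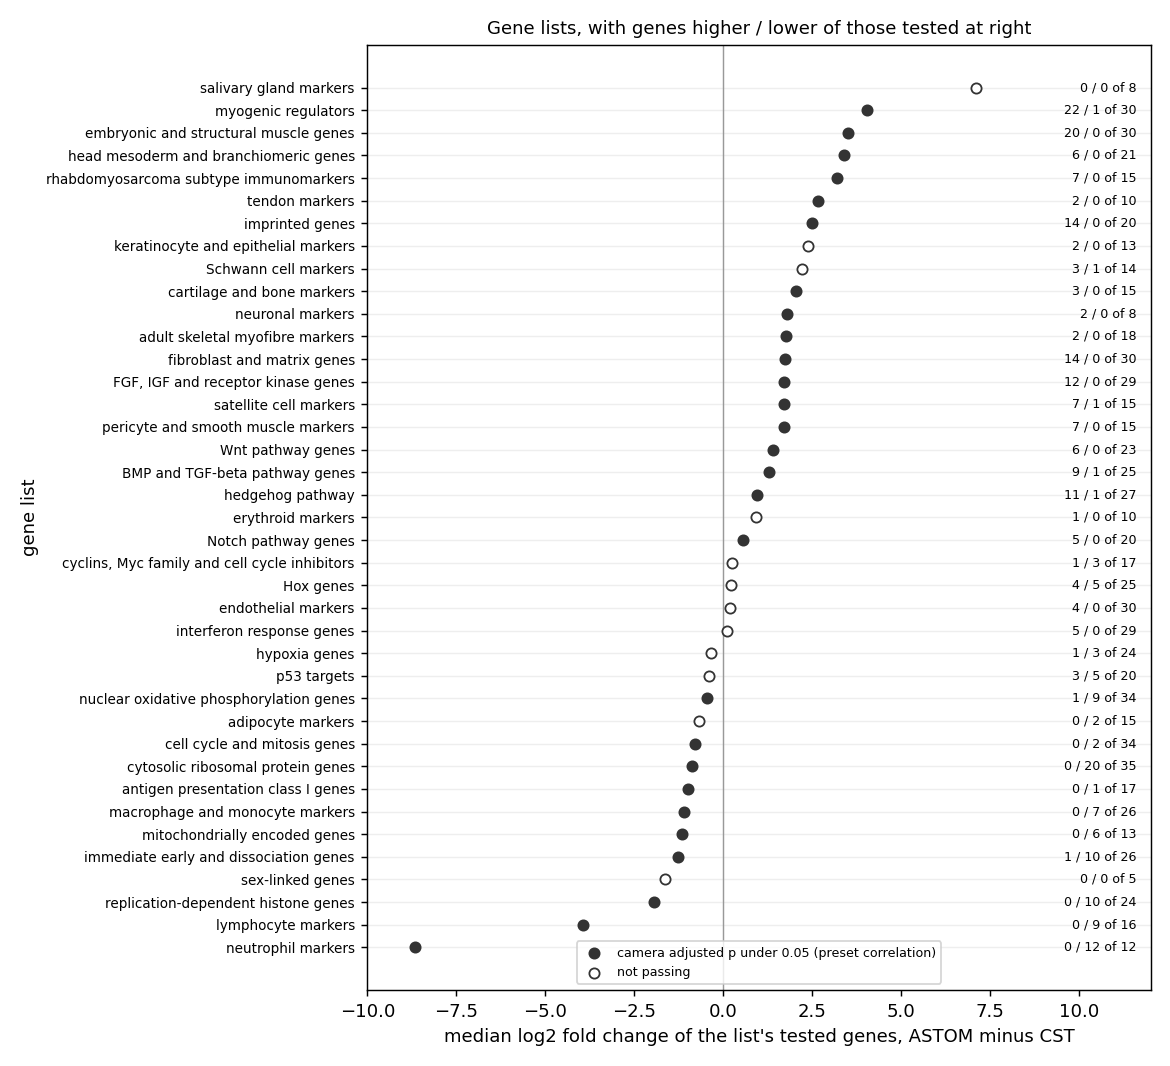
Median log2 fold change (ASTOM minus CST, horizontal axis) of the tested genes of each of 39 lists, with genes that have 0 counts in a model at their bound, filled where camera with a preset correlation gave an adjusted p under 0.05, and with the numbers of higher and lower genes at right. Myogenic regulators lie at 4.05 with 22 higher of 30, and neutrophil markers at -8.66 with 12 lower of 12. No list passed with an estimated correlation.

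The genes with the largest differences were mostly absent from the other model. Folds and ratios against 0 to 3 counts were computed from counts pooled over the libraries of each model, so that deeper libraries weigh more, while the levels given are mean CPM. Those higher in ASTOM included Lrtm1, a leucine-rich repeat membrane protein gene (66.3 ± 26.4 CPM and 0 counts in CST, at least 1697-fold higher when 3 counts over the model set the floor), Clrn1 (10.9 ± 2.85 CPM, at least 271-fold higher), Tlx1 (11.5 ± 5.69 CPM, at least 298-fold), Zic1 (10.9 ± 10.1 CPM, at least 306-fold) and Slco1a5 (11.7 ± 12.3 CPM, at least 335-fold). From mean CPM the bounds of these 5 genes were 1595, 261, 277, 262 and 282. Without ASTOM 7 the pooled bounds were 156 for Zic1 and 160 for Slco1a5. Slco1a5 lost its call without ASTOM 8, CST 5 or CST 6 (adjusted p 0.053, 0.0781 and 0.0582). Dcx, a microtubule protein gene of young neurons, was at 58.3 ± 16.7 CPM in ASTOM with 3 counts in CST, a pooled ratio of 1336 with a 95% counting interval of 457 to 6481, and 642 from mean CPM. Shisal1 was at 25.2 ± 5.42 CPM with 1 count in CST, a pooled ratio of 1844 with an interval of 331 to 72837, and 831 from mean CPM. AY036118 (chromosome 17, 39847113 to 39848035, minus strand), a long non-coding RNA annotated within ribosomal RNA sequence, was at 6415 ± 2813 CPM in ASTOM and at 0 in CST, at least 153620-fold higher. Its reads can be shared with ribosomal RNA genes, so that this difference is uncertain.

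Among the genes lower in ASTOM were the stefin genes Stfa2, Stfa3, Stfa2l1, Cstdc4 and Cstdc5, protease inhibitors of a clustered family on chromosome 16 that neutrophils express. Stfa3 had 0 counts in ASTOM and 5.96 and 17.3 CPM in CST (at least 432-fold lower), Stfa2 had 0 counts against 9.54 and 42.6 CPM (at least 864-fold lower) and Cstdc5 had 0 counts against 21.5 and 68.1 CPM (at least 1625-fold lower). From mean CPM these 3 bounds were 587, 1318 and 2264, and from CST 5 or CST 6 alone the pooled bounds were 301 or 872, 482 or 2154 and 1086 or 3441. For Stfa2l1 the values were 0.033 ± 0.0384 CPM against 20.96 and 90.3. Cstdc4 had 2 counts in ASTOM and 21.1 and 116 CPM in CST, a pooled ASTOM to CST ratio of 0.000308 (0.000198 from mean CPM) with a 95% counting interval of 3.73e-05 to 0.00111. Members of the family share sequence, and those other than Stfa3 had counts that were not whole. Wfdc21 was at 0.0487 ± 0.0568 CPM against 13.9 and 139 (edgeR adjusted p = 0.005). The histone gene Hist2h2aa1, which has a near-identical copy, had 0 counts in ASTOM against 4.56 and 20.3 CPM (at least 413-fold lower), and the non-coding Mirt2 0 counts against 0.539 and 33.8 CPM (at least 412-fold lower). From mean CPM the bounds were 629 for Hist2h2aa1 and 869 for Mirt2, and from CST 5 or CST 6 alone they were 230 or 1028 and 27.2 or 1710. Mirt2 lost its call without any of ASTOM 5 to 8 or CST 6 (adjusted p 0.0551 to 0.0713). These intervals and floors cover counting error only.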

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

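All tests in this part were chosen after the results were seen, except the test of whether genes with split reads are common among genes at 0 counts. Among the 4 ASTOM libraries, values were examined for a library far from the other 3 by Dixon's ratio, which chance exceeds in about 1 of 20 groups. In 10 of 135 values a library stood apart in this way, which is not far above the share that chance gives. The sex-linked sum, Xist and Ddx3y among them are not separate values. ASTOM 6 had 184 CPM of sex-linked genes in sum, against 2325 to 2555 in the other ASTOM libraries, with Xist, the X-inactivation RNA, at 0.934 CPM (others 2325 to 2555) and the Y-linked Ddx3y at 87.5 CPM (others 0). Both CST libraries resembled ASTOM 6, with Xist at 3.40 and 2.79 CPM and Ddx3y at 51.1 and 68.0. ASTOM 7 stood apart for Cdon (261 CPM, others 195 to 202), Dkk2 (55.0 CPM, others 19.1 to 24.8), mt-Nd3 (7.01 CPM, others 3.70 to 4.23) and mt-Atp8 (0.1001 CPM from 5 counts, others 0). ASTOM 8 stood apart for Fabp4 (28.2 CPM, others 7.53 to 10.8) and Retnlg (6.38 CPM, others 1.09 to 1.83), and ASTOM 5 for H2-D1 (492 CPM, others 195 to 221).

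The myogenic genes were low in CST, and technical explanations were set against this. Dilution of the CST libraries by blood cells would lower the genes of the other cells alike, where blood cells do not express them. The median log2 fold change of the myogenic regulators exceeded that of the fibroblast and matrix genes by 2.31. The 95% bootstrap interval over genes was 1.87 to 3.18 and holds no spread between libraries. The myogenic median also exceeded that of 4 hedgehog targets by 4.60 in CST 5 and 2.12 in CST 6. These values argue against dilution as the whole cause. The sex of the libraries is argued against by ASTOM 6, which matched CST in its sex-linked genes and still lay above the CST mean by a median of 3.94 on the log2 scale over the 30 regulators, although the lowest of the 4 ASTOM libraries (highest 4.40). A library or processing batch cannot be told apart from the model, since no batch holds both, and the share of detected genes with counts that were not whole, 15.8% on average in ASTOM and 32.5% in CST, differed in the same way. The difference in Cre driver stays open and untested.

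The neutrophil genes were high in CST, mostly in CST 6, in cells sorted with a gate for CD31-negative, tdTomato-positive cells. Blood cells among the sorted cells are a candidate source that stays open, since the count of 12 of the 12 markers higher in both CST libraries than in any ASTOM library restates the pattern and does not test its source. The most abundant markers were S100a9 (1118 and 24335 CPM) and Ngp (80.6 and 11476 CPM). None of the 12 is in another list, and 4 of them reach a mean of 10 CPM in ASTOM. Whether such cells carried the reporter or passed the gate without it cannot be told apart, because the tables hold 0 rows for the reporter or Cre.

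The other pattern concerns 763 called genes with counts in a single model, 711 at 0 in CST and 52 at 0 in ASTOM, together with mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8, which are near 0 in ASTOM. A change of all mitochondrial transcripts alike is argued against by mt-Nd1, mt-Nd4, mt-Nd5 and mt-Cytb, whose log2 fold changes had a median of -0.46 (range -1.06 to -0.04), and by a median of -0.75 over the 9 genes other than the 4. A change of some transcripts stays open, since mt-Nd3 among the 9 was lower by a log2 fold change of -3.84 with whole counts. However, mt-Nd3 lies beside mt-Co3, and Gm28438 lies beside the chromosome 1 copies named next. Gm28438 was at 3.13, 2.94, 6.11 and 4.96 CPM in ASTOM 5 to 8 and at 0 in CST. Even with all reads of Gm28438 added, mt-Nd3 (3.70 to 7.01 CPM in ASTOM) would stay below its 82.7 and 52.0 CPM in CST. These values argue against assignment to Gm28438 as the whole cause of the mt-Nd3 difference. Assignment of mt-Nd3 reads to other copies was not tested. Assignment of the 4 genes' reads to near-identical copies on chromosome 1 (Gm28437, Gm10925 and Gm28661, between 24613189 and 24615565) remains open, since the log2 ratio of -10.42 for the 4 genes (means 2.05 and 2797 CPM) was -1.02 with the 3 copies added (2358 and 4769 CPM), between the bounds of 1 and 2 set for and against it, and adding copies that edgeR did not call different between the models (adjusted p 0.209 to 0.59) shrinks such a ratio by itself. Read sharing also remains open, because the test of it turned out void, in that a count of 0 is always whole and 711 of the genes are at 0 in CST, where counts that were not whole were the more common, so that the odds ratio of 0.27 (95% interval 0.22 to 0.32; 16.1% against 41.9% of genes) and that of 0.31 within 10 classes of expression level lie below 1 by construction. Pseudogenes were more common among the 763 (42.2% against 9.0%), which leaves a difference in processing between the models open.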

How the results depend on the processing

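The fits to whole-count genes, to protein-coding genes and to the libraries with Y-linked counts were chosen after seeing the data. Of 2624 higher and 2045 lower genes, a mean of at least 5 CPM gave 1604 and 1595 (50.1% of calls higher, against 56.2%), a test against a fold of 1.5 gave 1906 and 1285, DESeq2 gave 4114 and 3086, and voom with sample weights 219 and 657 (218 and 644 of them shared). Leaving out 1 library gave 1016 to 3455 higher and 697 to 3030 lower genes, lowest without ASTOM 8 and highest without CST 5. A lone CST library is assumed there to vary like the ASTOM libraries. The title number as a replicate block, for which ASTOM 7 and 8 have no partner, gave 613 higher and 377 lower genes (567 and 354 shared). The numbers were not taken to pair libraries, because the labels do not state that a shared number marks a shared animal, litter or day. Deviations of same-numbered libraries correlated at -0.005 and 0.009. With 2 CST libraries the CST deviations mirror each other, so that differently numbered libraries gave 0.005 and -0.009. These values therefore do not decide the pairing. Of the 37 lists with a call, the block gave over 1.5 times fewer calls in 25 and more in 1, with counts of 18 against 22 for higher myogenic regulators, 12 against 20 for embryonic and structural muscle genes, 4 against 11 for hedgehog genes, 12 against 12 for lower neutrophil markers and 0 against 20 for ribosomal protein genes. Such falls came in 33 lists with sample weights, 17 with whole-count genes, 13 with the fold of 1.5, 5 with the mean of 5 CPM and 7 to 26 with an ASTOM library left out. Rises came in 11 lists with DESeq2, 3 without ASTOM 5, 2 without a filter and 2 with voom without weights. Fits with 1 library in a model also moved the numbers of calls, with falls and rises without CST 5 or CST 6 and falls in most lists with the Y-linked libraries. Whole-count genes gave 1646 and 1104, protein-coding genes 1714 and 1547, and the 3 libraries with Y-linked counts, 1 of ASTOM and 2 of CST, 91 and 66. The other alternatives stayed within 1.5 times of both counts. The median log2 fold change of all tested genes, 0.055, was 0.15 with upper-quartile factors, 0.168 with voom and 0.44 without a filter. With an estimated correlation 0 of 27 lists passed, and 18 to 30 passed under each other alternative run on the lists, which left out DESeq2, voom and the fold of 1.5. The cell cycle list reversed without CST 6, to a median of 0.587, and was at -1.292 without CST 5. Of the comparisons of named genes with an alternative, 2040 kept their side of the threshold, 298 lost their call and 12 gained it. Direction reversed in 0 comparisons in which either fit called the gene. A change of sign in a gene that neither fit called was counted among the 2040. The cause of these shifts was not tested, except that fewer genes or libraries entered the stricter filters and the fits without a library. The similarity difference of 0.1181 was 0.1381 with Pearson correlation. Another prior count left every rank and thus the Spearman values as they were, and the 500 most variable genes (1.1171) are chosen partly for the difference between models, so neither tests its stability. In the simulation, in which far fewer genes changed than were called in the data, changes of 4-fold were called in 33 of 100 genes.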

Other observations

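No test in this part was chosen after the results were seen, although several of the genes were. The Hox genes, which mark position along the body, did not pass as a list (camera adjusted p = 0.38), and 16 of the 25 tested did not pass edgeR. Higher in ASTOM were Hoxa2 (6.38 ± 3.37 CPM, SD, n = 4, against 0.593 and 0.787), Hoxa3 (9.33 ± 6.63 against 0.485 and 0.666), Hoxa4 (0 counts in CST, at least 37.9-fold higher with pooled counts and a floor of 3 counts over the model, or 33.7-fold from mean CPM and 22.7-fold without ASTOM 7) and Hoxb2 (2.53 ± 1.07 against 0 and 0.0606, a ratio of 190 from pooled counts with a 95% counting interval of 33.9 to 7524, and 83.7 from mean CPM). Lower in ASTOM were Hoxa9 (0.0145 ± 0.029 against 4.01 and 5.21, a pooled ratio of 0.00308 with an interval of 0.000372 to 0.0112) and Hoxa10 (0.00725 ± 0.0145 against 1.98 and 1.21, a pooled ratio of 0.00366 with an interval of 9.2e-05 to 0.0208). Hoxc10, Hoxc11 and Hoxd10 had 0 counts in ASTOM and were at least 66.5-fold, 79.8-fold and 102-fold lower (92.6, 118 and 153 from mean CPM, and 44.5, 47.2 and 59.0 from CST 5 alone). The counts of Hoxa3, Hoxa4, Hoxb2 and Hoxd10 were not whole in every library, so these genes can share reads with neighbours. All 9 had edgeR adjusted p-values under 0.05, from 0.00788 to 0.0237. Without ASTOM 7 there was 1 higher gene, with an adjusted p of 0.0501 for Hoxb2, and without ASTOM 8 or CST 5 there were 2. Hoxa2, Hoxa3, Hoxa4, Hoxc10, Hoxc11 and Hoxd10 were named after their values were seen.

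Salivary gland genes appeared in some ASTOM libraries. Muc19 was at 54.9 CPM in ASTOM 6 and 295 in ASTOM 8, at 3.08 in ASTOM 5 and at 0 in ASTOM 7 and both CST libraries. The mucin gene Muc5b, named after its values were seen, was the highest protein-coding gene of ASTOM 8 at 9089 CPM, with 1929 in ASTOM 6, 118 in ASTOM 5, 0.34 in ASTOM 7 and 0.79 and 0.242 in CST 5 and 6. The list's fitted median log2 fold change of 11.04 (7.10 with genes at 0 counts at their bound) covered 8 genes. Without ASTOM 6 and without ASTOM 8 the filter left 4 genes, with medians of 1.11 and 0.24, which are not comparable with it.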
